A study of Mus musculus with 9 samples.

How the data were processed

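Brain tissue of C57BL/6 wild-type mice was profiled by RNA sequencing 72 hours (3 days) after a sham procedure, intracerebral haemorrhage (ICH), or ICH with pterostilbene (PTE). Pterostilbene is a dimethylated analog of resveratrol, a plant stilbenoid. Each group held 3 mice, which were picked at random from the group's animals per the series design, and each mouse gave 1 library, 9 in all. The dose and route of PTE, the way in which ICH was made, the hemisphere and the brain region are not given in the sources used here. Per the labels' protocols, total RNA with an RNA integrity number over 7 was selected with oligo(dT) and made into libraries that keep the strand by a dUTP method. Groups and replicate numbers were taken from the labels. The numbers name different mice, so no pairing entered the fits.

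The authors deposited 1 table for the whole series with an FPKM value (fragments mapped to a gene, scaled by transcript length and by the mapped total) for each of 36346 genes in each of the 9 libraries. Each FPKM column was matched to its library by name, and 0 columns were left unmatched. Reads were handled with cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d, per the submitters' processing notes. The genome build is not given in the sources used here. The start and end of 33201 of the 36224 genes with a shared identifier (91.7%) were the same as in GENCODE M21 (GRCm38), and coordinates are printed as the deposited table gives them. GO cells of 2254 genes (1799 of them tested) and KEGG cells of 6 genes were not used here. FPKM values are not counts, so no count model was used.

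Depth was estimated from the step between low values of single-exon genes in each library. The step was sought only within a preset range, which bounds the depths that could come out. The estimates were 16.5, 17.3 and 18.6 M read units in the sham libraries, 16.6, 16.5 and 16.2 M in ICH, and 15.5, 16.1 and 15.9 M in ICH+PTE. Between 7.55% and 10.3% of the low values were whole multiples of this step and between 15.5% and 18.8% were whole multiples or midway between multiples, with a tolerance of 0.02 of a step. Whole reads could therefore not be recovered, the depths are estimates, and no counting interval is given. The share of multiples that chance would give was not computed, so the depths are only a rough guide.

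Tests ran on log2(FPKM + 0.5) in R 4.3.3. Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 15376 genes. A change on this scale understates the change of low genes. limma 3.58.1 was fitted with 1 mean per group over all 9 libraries (6 residual degrees of freedom) and moderated with a mean-variance trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from this limma fit. All 3 differences between groups were tested, ICH minus sham, ICH+PTE minus ICH and ICH+PTE minus sham. A gene symbol found more than once was represented by the entry with the highest mean. These p-values measure the spread between mice of a group.

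Lists of genes were tested with limma's camera, which compares a list with all other tested genes, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. limma's fry was run beside it and tests whether the genes of a list move, on balance, in 1 direction. The 42 lists cover microglia and macrophages (homeostatic, disease-associated and phagocytic, border-associated, infiltrating), neutrophils, lymphocytes, cytokines, the NF-kappaB pathway, interferon-stimulated genes, inflammasome, complement, antigen presentation, astrocytes (homeostatic and reactive), neurons (striatal, cortical and hippocampal, thalamic and other subcortical, pan-neuronal and synaptic, activity-regulated), oligodendrocytes and their precursors, endothelium, mural cells and fibroblasts, choroid plexus, ependyma, erythroid cells, haem and iron handling, NRF2 targets, ferroptosis, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, mitochondrial dynamics, cell cycle, matrix, apoptosis and p53 targets, the unfolded protein response, heat shock, lysosome, cholesterol, ribosomal proteins and sex-specific transcripts. Of their 624 distinct genes 5 had no entry under the listed symbol and 568 were tested. Lists with at least 4 tested members entered the test, which were 41 of the 42. A gene low in sham was tested only where libraries of the other groups reached the filter. In lists of such genes, the share of tested members that rose is partly set by this filter. GO and KEGG terms of the deposited table with 15 to 300 tested genes were tested in the same way in the first 2 comparisons.

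The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. For each comparison the rule takes the 8 called genes with the largest rise and the 8 with the largest fall among genes with a mean FPKM of at least 2 in the higher group and with no overlap between the groups, leaving out predicted genes and pseudogenes. It adds up to 4 called members of each list with the largest change, or the 2 most abundant members where none was called, and a panel of 16 genes (Hmox1, Lcn2, Gfap, Il1b, Ccl2, Spp1, Trem2, P2ry12, Tmem119, Nlrp3, Nqo1, Slc7a11, Gpx4, Drd1, Drd2 and Mbp). The rule names haemoglobin, histocompatibility, Ifi, Ly6, ribosomal protein and Hspa1 genes as uncertain, since family members share reads. The other-organ, glucocorticoid-induced and clock genes are outside this rule, were chosen later from general knowledge of these genes, and are used as groups.

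The position of each library between sham and ICH was computed from held-out libraries. Each of the 9 pairs of 1 sham and 1 ICH library was held out in turn, called genes and their changes were taken from the other libraries, and the held-out and ICH+PTE libraries were placed on a scale with sham at 0 and ICH at 1. Positions were compared by a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. Overlaps between comparisons that share libraries were set beside 100 simulated data sets with no group effect and beside the overlap of independent lists.

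The steps were tested on simulated data with 15376 genes, of which 200 were changed. In ICH minus sham 76% of 100 genes changed by 1 on the log2 scale and 98% of 100 changed by 2 were recovered, in ICH+PTE minus ICH 90% and 97%, and in ICH+PTE minus sham 84% and 99%. False calls made up 4.40%, 4.59% and 6.63% of calls in these comparisons. A simulated list of 20 genes changed by 0.7 was called by camera in each comparison. The simulated genes were drawn independently, so this does not test camera on lists whose genes move together. Simulated positions of 25% and 50% of the way to ICH came out at 26.5% and 50.3%.

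The alternatives were a pseudocount of 1 or 0.1, no filter or a mean FPKM of at least 5, quantile normalization, rescaling by the median of ratios, TPM, removal of haemoglobin and mitochondrially encoded genes, only the 2 groups compared, array weights, robust moderation, the replicate number as a block, an estimated correlation, fry, the 500 genes of smallest p for the position, and leaving out each library in turn. Added after seeing the data were a fit with 2 libraries per group, without the library of each group with the most Ttr, a fit with 1 treated library, and further settings for terms, opposite calls and the position.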

Results

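Expression of 15376 genes was compared between brain samples taken 72 hours after sham surgery, ICH, or ICH with PTE, with 3 mice in each group. The estimated depth was 16.5 to 18.6 M read units per sham library, 16.2 to 16.6 M per ICH library and 15.5 to 16.1 M per ICH+PTE library. These depths are a rough guide, since the step behind them was sought only within a preset range. The first principal component of log2(FPKM + 0.5) held 71.5% of the variance and the second 14.4%. Mitochondrially encoded transcripts made up 21.7% to 22.9% of the summed FPKM in sham, 13.6% to 16.7% in ICH and 25.5% to 28.9% in ICH+PTE libraries. The comparisons ask what ICH changed in the brain at this time, whether mice given PTE differed from mice with ICH alone, and what still set them apart from sham. Values are mean FPKM ± SD over 3 mice, changes are differences of log2(FPKM + 0.5), and ± after a change is its standard error. As examples of position, Spp1 (chromosome 5, 104435118 to 104441050), Hmox1 (chromosome 8, 75093621 to 75100589), Slc17a7 (chromosome 7, 45163949 to 45176142), Serpina3n (chromosome 12, 104406729 to 104414329) and Drd1 (chromosome 13, 54051183 to 54055705) are given by the deposited coordinates, whose build is not given in the sources used here.

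At 72 hours after ICH the brain samples were filled with transcripts of phagocytes and poor in transcripts of neurons. Spp1, which encodes the secreted phosphoprotein osteopontin, stood at 52.6 ± 31.9 FPKM in sham and 5266 ± 907 in ICH (mean ± SD, n = 3 each), a log2 difference of 6.78 ± 0.52 (limma adjusted p = 4.12e-06). Hmox1, the enzyme that breaks down haem, rose from 14.6 ± 9.78 to 493 ± 64.2 FPKM (5.33 ± 0.50, adjusted p = 1.34e-05). Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, fell from 41.4 ± 7.54 to 6.46 ± 4.32 FPKM (-2.81 ± 0.48, adjusted p = 5.16e-04). Genes of reactive astrocytes, dividing cells, extracellular matrix and ribosomes rose together with those of phagocytes. None of these list calls held with an estimated correlation, where the adjusted p was 0.206 for reactive astrocytes, 0.325 for the cell cycle, 0.206 for matrix, 0.325 for ribosomal proteins, 0.206 for phagocytes and 0.259 for pan-neuronal genes.

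The 8 largest rises that met the rule for named genes were Spp1 (6.78), Arg1 (6.75), Pf4 (6.45), Wfdc17 (6.20), Lgals3 (5.95), Lyz2 (5.77), Gpnmb (5.74) and Apoc2 (5.51), where the numbers are log2 differences. Most of them are known from macrophages. Arg1, an arginase of alternatively activated macrophages, rose from 0.863 ± 0.465 to 143 ± 39.7 FPKM, and Lyz2, the lysozyme of myeloid cells, from 51.1 ± 15.8 to 2734 ± 330 FPKM. The 8 largest falls were Lbhd2 (-3.13), Neurod6 (-2.82), Slc17a7 (-2.81), Gabrb2 (-2.56), Egr3 (-2.47), Ngb (-2.45), Baiap3 (-2.42) and Calb2 (-2.39). Neurod6 is a transcription factor of excitatory neurons, Gabrb2 a subunit of the GABA-A receptor and Ngb the neuronal globin.

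Every tested gene of phagocytic and disease-associated microglia or macrophages rose, 19 of 19 (median log2 difference 3.43, camera adjusted p = 2.11e-10, adjusted p = 0.206 with an estimated correlation). All 14 tested genes of infiltrating monocytes (3.26, adjusted p = 4.88e-08, adjusted p = 0.206 with an estimated correlation) rose. So did all 6 tested of the 9 listed genes of border-associated macrophages (4.18, adjusted p = 5.05e-05, adjusted p = 0.206 with an estimated correlation). Genes of homeostatic microglia were higher in 9 of 13 and lower in 0 (1.32, adjusted p = 0.00337, adjusted p = 0.552 with an estimated correlation). Tmem119 was at 2.07, while the purinergic receptor P2ry12 was not called (0.26, adjusted p = 0.145; 0.0387 without ICH+PTE 1, 0.0483 with only the 2 groups compared and 0.0486 with ICH+PTE 3 as the only treated library). The 6 tested of 14 listed neutrophil genes all rose (2.47, adjusted p = 7.94e-04, adjusted p = 0.206 with an estimated correlation). Among them were the calprotectin subunit S100a9 (3.64) and the collagenase Mmp8 (3.91). Of lymphocyte markers only 3 were tested, too few for camera: the B cell receptor gene Cd79b was higher (1.72) and Cd4 lower (-1.18), and Trac was called at 0.99, a call that was lost without single libraries (adjusted p = 0.113 without sham 2, 0.0887 without sham 3, 0.0572 without ICH 1, 0.0802 without ICH 2 and 0.102 without ICH 3). It was also lost with a pseudocount of 0.1 (0.0546), with all genes above 0 tested (0.116), with quantile normalization (0.80, 0.0568), with TPM (0.0581) and without haemoglobin and mitochondrially encoded genes (0.79, 0.0884).

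Inflammatory signalling genes moved the same way. All 15 tested of the 21 listed cytokine and chemokine genes rose (median log2 difference 2.73, camera adjusted p = 4.72e-07, adjusted p = 0.206 with an estimated correlation). Ccl2, a chemokine that draws monocytes, went from 0.573 ± 0.217 to 19.9 ± 1.06 FPKM. All 15 genes of the NF-kappaB pathway rose (1.5, adjusted p = 5.14e-07, adjusted p = 0.206 with an estimated correlation). All 12 complement genes rose (2.64, adjusted p = 3.61e-07, adjusted p = 0.206 with an estimated correlation). Antigen presentation genes rose in all 12 (3.02, adjusted p = 1.47e-07, adjusted p = 0.206 with an estimated correlation). C1qb, a chain of the complement initiator C1q, rose by 3.87 and Cd74, the invariant chain of class II molecules, by 4.66. Interferon-stimulated genes were higher in 19 of 20 (1.66, adjusted p = 5.14e-07, adjusted p = 0.231 with an estimated correlation), with the membrane protein Bst2 at 3.53. Of the 11 inflammasome genes 10 rose and 1 fell (1.59, adjusted p = 5.23e-04, adjusted p = 0.206 with an estimated correlation), with the adaptor Pycard at 2.97, the sensor Nlrp3 at 1.44 and the cytokine Il1b at 2.24.

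All 20 tested genes of the reactive astrocyte list rose (median log2 difference 2.46, camera adjusted p = 3.26e-09, adjusted p = 0.206 with an estimated correlation). Gfap, the astrocyte intermediate filament, went from 154 ± 60.0 to 665 ± 43.3 FPKM. Lcn2, an iron-siderophore carrier, rose from 3.68 ± 3.11 to 88.3 ± 17.0 FPKM. Serpina3n, a serine protease inhibitor, rose from 37.9 ± 17.8 to 529.8 ± 23.2 FPKM. Homeostatic astrocyte genes went both ways, 5 higher and 4 lower of 13, and the list was not called (adjusted p = 0.940). All 11 genes of oligodendrocyte precursors rose (1.10, adjusted p = 0.00110, adjusted p = 0.206 with an estimated correlation), with the receptor Gpr17 at 1.34. Mature myelin genes were higher in 3 of 14 and not called as a list (median 0.41, adjusted p = 0.262). The list was called higher without sham 1 (median 0.68, adjusted p = 0.0423) and with 2 libraries per group (0.68, 0.0258). Mbp, the myelin basic protein, stood at 411 ± 159.7 and 565 ± 115 FPKM and was not called (0.50, adjusted p = 0.101; 0.00568 without sham 1, 0.0223 with array weights and 0.0187 with 2 libraries per group). Endothelial genes were higher in 10 of 14 (0.68, adjusted p = 0.00162, adjusted p = 0.271 with an estimated correlation). Genes of mural cells and fibroblasts were higher in 12 of 13 (2.13, adjusted p = 7.16e-06, adjusted p = 0.206 with an estimated correlation), with the fibrillar collagen Col3a1 at 4.93. All 17 matrix and matrix protease genes rose (3.36, adjusted p = 2.53e-09, adjusted p = 0.206 with an estimated correlation), among them the elastase Mmp12 (4.96).

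Haem and iron genes were higher in 14 of 18 (median log2 difference 1.5, camera adjusted p = 1.32e-04, adjusted p = 0.206 with an estimated correlation), and Ftl1, the ferritin light chain, rose by 4.15. NRF2 targets and antioxidant enzymes were higher in 12 and lower in 2 of 20 (0.47, adjusted p = 0.00469, adjusted p = 0.206 with an estimated correlation). In that list the peroxidase Gpx1 rose by 2.16, while Nqo1 (0.41, adjusted p = 0.0593; 0.0103 without ICH 3, 0.0369 with the replicate block and 0.0465 with the median of ratios) and the cystine transporter subunit Slc7a11 (-0.15, adjusted p = 0.486) were not called. Slc7a11 was called lower with array weights (-0.33, adjusted p = 0.0394) and with 2 libraries per group (-0.41, 0.0266). Lysosome and autophagy genes were higher in 14 of 17 (1.79, adjusted p = 4.06e-06, adjusted p = 0.206 with an estimated correlation), with the protease Ctsd at 4.05. All 19 cell cycle genes rose (2.34, adjusted p = 2.47e-07, adjusted p = 0.325 with an estimated correlation). Higher values were called in 10 of 13 apoptosis and p53 genes (0.91, adjusted p = 7.87e-04, adjusted p = 0.206 with an estimated correlation). All 27 ribosomal protein genes rose (1.20, adjusted p = 2.39e-09, adjusted p = 0.325 with an estimated correlation), though reads of ribosomal protein genes can be shared with their pseudogenes. Ferroptosis genes were higher in 7 of 12 (0.54, adjusted p = 0.0422, adjusted p = 0.206 with an estimated correlation), with Gpx4, which reduces lipid peroxides, at 0.79. The list lost the call without sham 1 (0.0674) or ICH+PTE 1 (0.0528). Glycolysis genes were higher in 11 of 16 (0.51, adjusted p = 0.0422, adjusted p = 0.206 with an estimated correlation). That call was lost without sham 1 (0.0674), with quantile normalization (0.439), with TPM (0.0550) and without haemoglobin and mitochondrial genes (0.0740). Genes of the unfolded protein response were higher in 8 of 13 (0.57, adjusted p = 0.0276, adjusted p = 0.552 with an estimated correlation). That call was lost without sham 1 (0.0680). Ferroptosis and glycolysis also lost their calls with 2 libraries per group (0.0908 and 0.0555) and with ICH+PTE 3 as the only treated library (0.0526 and 0.0526).

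Neuronal genes fell. Of the 22 pan-neuronal and synaptic genes 20 fell and 1 rose (median log2 difference -1.40, camera adjusted p = 3.61e-07, adjusted p = 0.259 with an estimated correlation). Syt1, the calcium sensor of synaptic vesicles, went from 104 ± 9.77 to 27.6 ± 6.00 FPKM. All 16 genes of striatal projection neurons fell (-1.33, adjusted p = 1.30e-05, adjusted p = 0.349 with an estimated correlation). The dopamine receptors Drd1 and Drd2 were at -1.57 and -1.25 and the phosphodiesterase Pde10a at -1.76. Genes of cortical and hippocampal excitatory neurons were lower in 10 of 12 (-1.32, adjusted p = 0.00424, adjusted p = 0.302 with an estimated correlation). Mitochondrially encoded transcripts were lower in 5 of 13 (-0.39, adjusted p = 0.0270, adjusted p = 0.634 with an estimated correlation), a call lost without sham 1 (0.0566) or ICH 3 (0.0672). The lists of nuclear-encoded oxidative phosphorylation (6 higher and 6 lower of 28), mitochondrial dynamics (2 and 8 of 15), activity-regulated genes (4 and 6 of 11), cholesterol (5 and 9 of 15), and thalamic and other subcortical neurons (2 and 3 of 12) were not called. Nor were heat shock (3 and 3 of 10), ependyma (1 and 4 of 9), choroid plexus (1 and 1 of 8), erythroid cells (2 and 1 of 5) and sex-specific transcripts (0 and 0 of 4). Mitochondrial dynamics (adjusted p = 0.0571) was called lower without single libraries (adjusted p = 0.0461 without ICH 1 and 0.0483 without ICH+PTE 2).

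In all, limma called 4862 genes higher and 4936 lower in ICH than in sham (63.7% of the 15376 tested), of which 2356 and 1696 changed at least 2-fold. The groups did not overlap for 73.5% of genes, where chance gives 10%. Removing haemoglobin and mitochondrially encoded genes before rescaling moved the median of all genes by -0.27 and gave 3486 higher and 7037 lower, and TPM moved the median by -0.15. Camera called 29 of 41 lists at the preset correlation, 25 higher and 4 lower, and fry called 31. With an estimated correlation camera called 0 lists. Counts of members adjusted over the list alone were the same as those over all genes in 38 of the lists, and differed for choroid plexus (1 and 0), the unfolded protein response (9 and 1) and heat shock (3 and 6). Median, mean and test differed in sign in 3 lists, none of them called. Among KEGG terms, Ribosome (107 of 129 genes higher, adjusted p = 4.65e-13) and Lysosome (73 of 113, 1.49e-08) were higher. So were Complement and coagulation cascades (34 of 50, 5.59e-08) and DNA replication (29 of 33, 5.43e-07). GABAergic synapse (59 of 77 lower, 1.80e-06) was lower. They were among 138 called KEGG and 213 called GO terms of 284 and 1267, and none (0) held with an estimated correlation, for Ribosome adjusted p = 0.444.

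**Figure D1:**
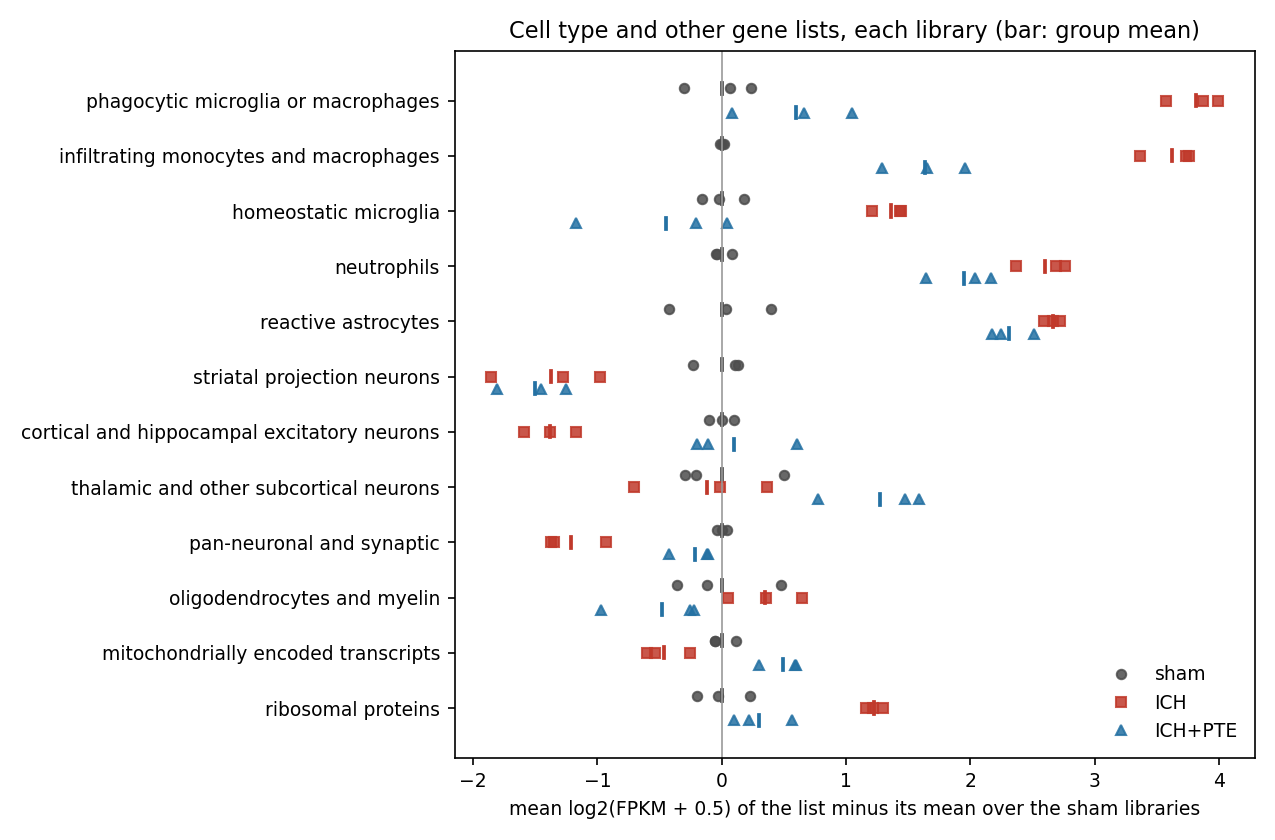
Mean log2(FPKM + 0.5) of 12 gene lists in each library, minus the mean over the sham libraries, with 1 point per library and a bar at each group mean. Phagocytic genes of ICH libraries lie far to the right of both other groups, reactive astrocyte genes are to the right in ICH and ICH+PTE, and striatal genes to the left in both.

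In ICH mice given PTE, phagocyte transcripts were far below those of ICH mice and neuronal transcripts far above, while the lists of reactive astrocyte and striatal neuron genes were not called. With an estimated correlation the adjusted p was 0.348 for phagocytic genes and 0.348 for pan-neuronal genes, which ends both calls. Spp1 stood at 194 ± 119.7 FPKM in ICH+PTE against 5266 ± 907 in ICH (mean ± SD, n = 3 each), a difference of -4.99 ± 0.52 (limma adjusted p = 4.97e-05). Trem2, a lipid receptor of microglia, fell from 69.9 ± 5.52 to 4.43 ± 2.41 FPKM (-3.96 ± 0.32, adjusted p = 1.50e-05), next to 4.74 ± 1.07 in sham. Slc17a7 rose from 6.46 ± 4.32 to 53 ± 25.6 FPKM (3.08 ± 0.48, adjusted p = 4.48e-04). Lcn2 did not follow, with 88.3 ± 17.0 FPKM in ICH and 94.8 ± 12.1 in ICH+PTE (0.11, adjusted p = 0.845).

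Transcripts of another organ and of other neurons moved with this comparison. The summed FPKM of 24 small-intestine genes was 7.43 to 19.4 in the ICH+PTE libraries and 0.124 to 0.443 in the other 6. Genes of thalamic and other subcortical neurons were higher in ICH+PTE than in ICH for 6 of 12 (median log2 difference 1.58, camera adjusted p = 0.00836, adjusted p = 0.361 with an estimated correlation), led by the calcium-binding protein Calb2 (2.86). They were higher than in sham for 6 (1.03, adjusted p = 0.00135, adjusted p = 0.293 with an estimated correlation).

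The 8 largest falls were Cd5l (-6.02), Fcrls (-5.72), Gpnmb (-5.50), Lyz2 (-5.46), Spp1 (-4.99), Clec7a (-4.72), Col1a1 (-4.70) and Wfdc17 (-4.44). Cd5l, a secreted protein of macrophages, went from 59.4 ± 11.7 to 0.483 ± 0.453 FPKM, and Fcrls, a microglial Fc receptor-like gene, from 201 ± 28.5 to 3.94 ± 2.54 FPKM. The 8 largest rises were Slc17a7 (3.08), Calb2 (2.86), Oxt (2.67), Slc30a3 (2.63), Rasgrf2 (2.59), Ngb (2.58), Zbtb16 (2.53) and AW551984 (2.47). Slc30a3 is the zinc transporter of synaptic vesicles and Zbtb16 a transcription factor induced by glucocorticoids. The call of Oxt, the oxytocin precursor, was lost without single libraries (adjusted p = 0.0756 without ICH 2 and 0.0608 without ICH+PTE 2). It was also lost with all genes above 0 tested (0.0763), with array weights (0.0902), with 2 libraries per group (0.0667) and with ICH+PTE 3 as the only treated library (0.194).

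All 19 phagocytic genes fell (median log2 difference -3.16, camera adjusted p = 1.91e-10, adjusted p = 0.348 with an estimated correlation). So did 13 of 14 genes of infiltrating monocytes (-1.67, adjusted p = 1.57e-05, adjusted p = 0.348 with an estimated correlation). Border-associated macrophage genes fell in 4 of 6 (-2.25, adjusted p = 0.00265, adjusted p = 0.348 with an estimated correlation). Homeostatic microglia genes fell in all 13 (-1.52, adjusted p = 5.36e-05, adjusted p = 0.404 with an estimated correlation). Antigen presentation genes fell in all 12 (-1.93, adjusted p = 1.19e-06, adjusted p = 0.348 with an estimated correlation). Complement genes fell in 10 of 12 (-1.15, adjusted p = 2.84e-04, adjusted p = 0.348 with an estimated correlation). Interferon-stimulated genes fell in 16 of 20 (-1.12, adjusted p = 4.21e-05, adjusted p = 0.361 with an estimated correlation). Of cytokine genes 12 of 15 fell (-1.31, adjusted p = 1.80e-04, adjusted p = 0.348 with an estimated correlation). Of NF-kappaB genes 12 of 15 fell (-0.92, adjusted p = 2.23e-04, adjusted p = 0.348 with an estimated correlation). Of inflammasome genes 9 of 11 fell (-1.18, adjusted p = 0.00318, adjusted p = 0.348 with an estimated correlation). Within these groups the class II chain H2-Ab1 changed by -3.80, an uncertain value since its family shares reads, C1qc by -3.23, Ccl2 by -1.49, Il1b by -1.23 and Nlrp3 by -0.86. Neutrophil genes were lower in 2 of 6 and not called as a list (adjusted p = 0.331).

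All 19 cell cycle genes fell (median log2 difference -1.59, camera adjusted p = 4.46e-06, adjusted p = 0.404 with an estimated correlation). Matrix genes fell in 14 of 17 (-1.69, adjusted p = 2.60e-05, adjusted p = 0.348 with an estimated correlation). Genes of mural cells and fibroblasts fell in 10 of 13 (-0.79, adjusted p = 0.00134, adjusted p = 0.348 with an estimated correlation). Lysosome and autophagy genes fell in 14 of 17 (-1.53, adjusted p = 2.90e-06, adjusted p = 0.348 with an estimated correlation). All 27 ribosomal protein genes fell (-0.89, adjusted p = 5.66e-08, adjusted p = 0.404 with an estimated correlation). Haem and iron genes were lower in 11 and higher in 1 of 18 (-0.80, adjusted p = 0.00664, adjusted p = 0.348 with an estimated correlation). Hmox1 itself, at 193 ± 56.5 FPKM in ICH+PTE, was called (-1.38 ± 0.50, adjusted p = 0.0359). The call was lost without single libraries (adjusted p = 0.0587 without ICH 1, 0.0759 without ICH 2, 0.0941 without ICH 3, 0.109 without ICH+PTE 1 and 0.0817 without ICH+PTE 3). It was also lost with all genes above 0 tested (0.116), with quantile normalization (-0.81, 0.184), without haemoglobin and mitochondrially encoded genes (-1.11, 0.0826) and with ICH+PTE 3 as the only treated library (0.150). Genes of oligodendrocyte precursors fell in 10 of 11 (-1.33, adjusted p = 7.77e-04, adjusted p = 0.348 with an estimated correlation). Gpr17 went from 43.9 ± 7.17 to 4.43 ± 2.40 FPKM, below its 16.9 ± 1.61 in sham. Myelin genes were lower in 8 of 14 (-0.81, adjusted p = 0.0245, adjusted p = 0.659 with an estimated correlation). That call was lost without ICH 2 (0.0679), without ICH+PTE 1 (0.0731) and with quantile normalization (0.0984) or ICH+PTE 3 as the only treated library (0.114). In that list Mbp was called at -0.81 (adjusted p = 0.0191). The call was lost without single libraries (adjusted p = 0.0734 without ICH 2, 0.0571 without ICH+PTE 1 and 0.0586 without ICH+PTE 3). It was also lost with all genes above 0 tested (0.0756), with quantile normalization (-0.10, 0.688), without haemoglobin and mitochondrially encoded genes (-0.53, 0.0660) and with ICH+PTE 3 as the only treated library (0.0784). Glycolysis genes were lower in 12 and higher in 3 of 16 (-0.70, adjusted p = 0.00648, adjusted p = 0.348 with an estimated correlation), lost with quantile normalization (0.0984). Genes of the unfolded protein response were lower in 9 of 13 (-0.65, adjusted p = 0.0458, adjusted p = 0.607 with an estimated correlation). That call was lost with quantile normalization (0.110) and without ICH 2 (0.0757), ICH+PTE 1 (0.0540) or ICH+PTE 3 (0.0704).

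Neuronal genes went the other way. Of the 22 pan-neuronal genes 18 rose (median log2 difference 1.16, camera adjusted p = 1.17e-06, adjusted p = 0.348 with an estimated correlation). Syt1 was at 93.5 ± 26.1 FPKM in ICH+PTE against 27.6 ± 6.00 in ICH. In addition 10 of 12 genes of cortical and hippocampal excitatory neurons rose (1.44, adjusted p = 1.88e-04, adjusted p = 0.348 with an estimated correlation). Mitochondrially encoded transcripts rose in all 13 (0.92, adjusted p = 3.40e-05, adjusted p = 0.375 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation were higher in 3 and lower in 8 of 28 and not called (adjusted p = 0.232). Genes of mitochondrial dynamics were higher in 10 and lower in 3 of 15 (0.44, adjusted p = 0.0177, adjusted p = 0.348 with an estimated correlation), among them the fission enzyme Dnm1l (0.95). Striatal projection neuron genes did not rise: 1 of 16, Adora2a (-0.93; adjusted p = 0.150 with ICH+PTE 3 as the only treated library and 0.0503 without haemoglobin and mitochondrially encoded genes), was called lower. The list was not called (-0.05, adjusted p = 0.826). The dopamine receptors stood at 0.11 (Drd1, adjusted p = 0.721) and -0.55 (Drd2, adjusted p = 0.131; 0.0214 without ICH 2). Reactive astrocyte genes were lower in 8 and higher in 2 of 20 and not called as a list (-0.35, adjusted p = 0.232). In it the filament gene Vim fell by 1.77 and the small heat shock protein gene Hspb1 rose by 1.18 (adjusted p = 0.00722; 0.217 with ICH+PTE 3 as the only treated library). Gfap was called at -0.67 (adjusted p = 0.0420). Quantile normalization gave 0.12 (0.710). The call was lost without single libraries (adjusted p = 0.0645 without ICH 1, 0.107 without ICH 2, 0.0883 without ICH 3, 0.143 without ICH+PTE 1 and 0.0932 without ICH+PTE 3). It was also lost with all genes above 0 tested (0.129), with TPM (0.0512), without haemoglobin and mitochondrially encoded genes (-0.40, 0.191), with array weights (0.0850), with 2 libraries per group (0.152) and with ICH+PTE 3 as the only treated library (0.115). Slc7a11 rose by 0.97, Gpx4, P2ry12 and Tmem119 changed by -0.84, -0.87 and -2.67, and Nqo1 was not called (0.05, adjusted p = 0.824). The lists of NRF2 targets (6 higher and 9 lower of 20), ferroptosis (4 and 6 of 12), apoptosis (0 and 7 of 13) and endothelium (2 and 6 of 14) were not called. Nor were homeostatic astrocytes (6 and 3 of 13), cholesterol (9 and 5 of 15), activity-regulated genes (2 and 3 of 11), heat shock (2 and 2 of 10), ependyma, choroid plexus and erythroid cells. Apoptosis genes (median -0.46, adjusted p = 0.0643) were called lower without ICH+PTE 1 (0.0163), with 2 libraries per group (0.0173) and with ICH+PTE 3 as the only treated library (0.010). That last fit also called erythroid genes higher (0.0293), a call that reflects ICH+PTE 3 alone. The list stood above the sham mean by 0.25, 0.56 and 2.82 in ICH+PTE 1 to 3.

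**Figure D2:**
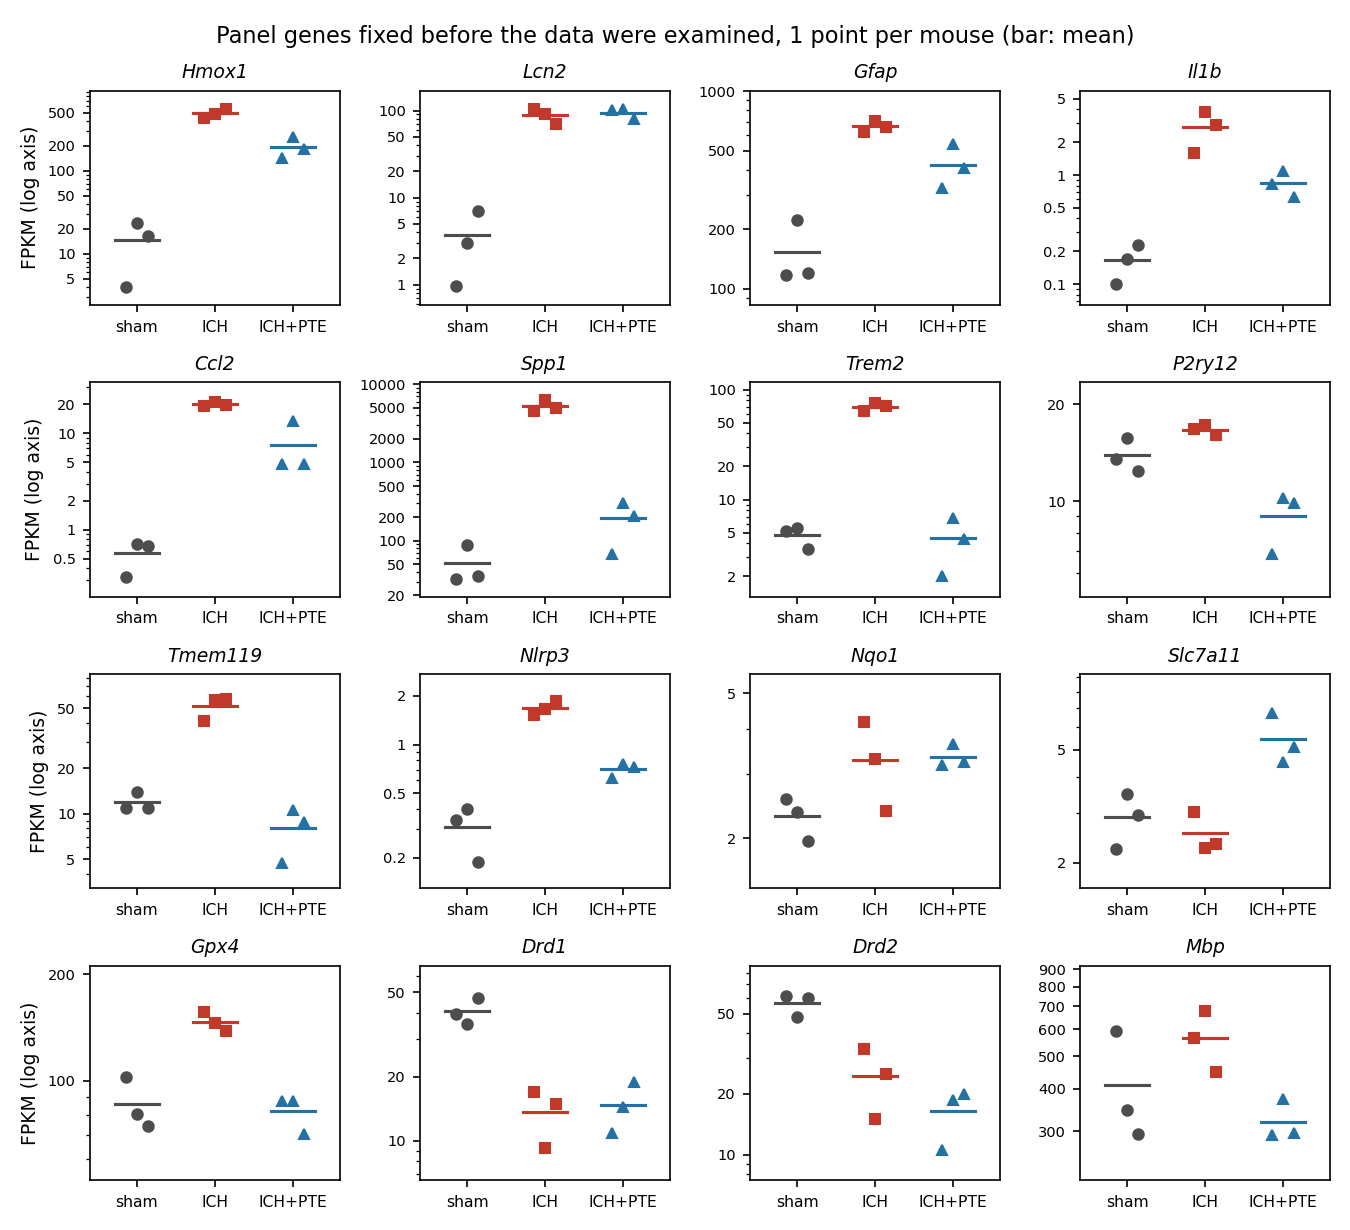
FPKM of the panel genes on log axes, with 1 point per mouse and a bar at the mean of each group (n = 3). Spp1 and Trem2 are highest in ICH, Lcn2 is high in ICH and ICH+PTE, and Drd1 is low in both.

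ICH+PTE differed from ICH in 4065 genes called higher and 4683 called lower (56.9% of those tested), 1022 and 1755 of them by at least 2-fold, and the groups did not overlap for 64.7% of genes against 10% by chance. Removing haemoglobin and mitochondrially encoded genes before rescaling moved the median by 0.24 and gave 6114 higher and 3149 lower. Camera called 5 lists higher and 20 lower of 41, fry called 28, and an estimated correlation left 0. Adjusted over the list alone, the counts were the same in 25 lists. Among the called lists they differed for border-associated macrophages (5 lower), interferon-stimulated (18), complement (11), oligodendrocyte (9), haem (2 higher and 11 lower) and matrix genes (1 and 15), cortical (11 higher), thalamic (5) and pan-neuronal genes (19 and 1), precursors (1 and 10), mural cells (1 and 10) and mitochondrial dynamics (11 and 3). Among the others they differed for striatal (0 and 0), activity-regulated (2 and 1) and endothelial genes (3 and 6) and NRF2 targets (6 and 11). KEGG terms moved opposite to the first comparison, with Ribosome lower in 109 of 129 genes (adjusted p = 5.17e-12), Lysosome in 80 of 113 (1.60e-09) and Glutamatergic synapse higher in 65 of 102 (3.04e-05). These belong to 119 called KEGG and 160 called GO terms, of which 0 held with an estimated correlation (for Ribosome adjusted p = 0.488).

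Set against sham, the lists of reactive astrocyte, monocyte, endothelial and matrix genes were called higher in ICH+PTE mice and that of striatal neurons lower. None of these calls held with an estimated correlation, where the adjusted p was 0.172 for reactive astrocytes, 0.187 for monocytes, 0.235 for endothelium, 0.187 for matrix and 0.241 for striatal neurons. Phagocytic genes lay closer to sham. Serpina3n stood at 494 ± 43.2 FPKM in ICH+PTE and 37.9 ± 17.8 in sham (mean ± SD, n = 3 each), a difference of 3.78 ± 0.25 (limma adjusted p = 4.17e-05). Lcn2 rose by 4.81 ± 0.46 (adjusted p = 1.83e-04) and Hmox1 by 3.94 ± 0.50 (adjusted p = 7.54e-04). Rgs9, a striatal regulator of dopamine receptor signalling, differed by -2.12 ± 0.24 (adjusted p = 4.85e-04). Trem2 was not called (-0.19, adjusted p = 0.693).

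The 8 largest rises were Pmch (6.25), Lcn2 (4.81), Rps3a2 (4.72), Arg1 (4.37), Timp1 (4.18), Ctla2a (4.14), Ms4a4a (4.04) and Hmox1 (3.94). Pmch, the melanin-concentrating hormone precursor of the lateral hypothalamus, stood at 178 ± 159.9 FPKM in ICH+PTE and 0.796 ± 0.647 in sham. Its call was lost without single libraries (adjusted p = 0.0554 without sham 1, 0.0736 without sham 2, 0.0858 without sham 3, 0.0881 without ICH+PTE 2 and 0.0770 without ICH+PTE 3). It was also lost with all genes above 0 tested (0.107), with robust eBayes (0.0566) and with ICH+PTE 3 as the only treated library (0.0930). Rps3a2 is a copy of a ribosomal protein gene and is uncertain. The 8 largest falls were Mup7 (-4.28), Mup12 (-4.14), Serpina1e (-3.10), Fcrls (-2.60), Rxrg (-2.56), Hes5 (-2.47), Mup3 (-2.41) and Gpr52 (-2.38). Mup7, Mup12, Mup3 and Serpina1e are abundant liver transcripts. The Mup genes share reads and are uncertain, and the call of Mup3 was lost with ICH+PTE 3 as the only treated library (0.198). Rxrg, a retinoid receptor found in striatal neurons, went from 32.9 ± 7.80 to 5.46 ± 2.33 FPKM.

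All 20 reactive astrocyte genes were higher than in sham (median log2 difference 1.88, camera adjusted p = 1.12e-19, adjusted p = 0.172 with an estimated correlation), with Gfap at 1.5 and Timp1, an inhibitor of matrix metalloproteinases, at 4.18. Neutrophil genes were higher in 5 of 6 (1.88, adjusted p = 4.22e-05, adjusted p = 0.140 with an estimated correlation), with S100a9 at 13.5 ± 4.91 FPKM in ICH+PTE, 11.6 ± 4.06 in ICH and 0.474 ± 0.330 in sham. Infiltrating monocyte genes were higher in 10 of 14 (1.26, adjusted p = 1.32e-08, adjusted p = 0.187 with an estimated correlation). Border-associated macrophage genes were higher in 5 of 6 (1.97, adjusted p = 4.59e-06, adjusted p = 0.187 with an estimated correlation). Complement genes were higher in 9 of 12 (1.49, adjusted p = 4.32e-08, adjusted p = 0.189 with an estimated correlation). Cytokine genes were higher in 8 of 15 (1.0, adjusted p = 2.04e-06, adjusted p = 0.189 with an estimated correlation), with Ccl2 at 2.78. NF-kappaB genes were higher in 10 of 15 (0.83, adjusted p = 8.53e-07, adjusted p = 0.187 with an estimated correlation). Antigen presentation genes were higher in 7 of 12 (0.89, adjusted p = 6.44e-06, adjusted p = 0.305 with an estimated correlation). Interferon-stimulated genes were higher in 5 of 20 (0.48, adjusted p = 3.18e-04, adjusted p = 0.462 with an estimated correlation). Inflammasome genes were higher in 4 of 11 (0.50, adjusted p = 0.00366, adjusted p = 0.326 with an estimated correlation; median 0.26 without ICH+PTE 2). Phagocytic genes were higher in 7 and lower in 1 of 19, with a small median (0.40, adjusted p = 0.00331, adjusted p = 0.638 with an estimated correlation). The library means against sham were 0.08, 1.05 and 0.66 in ICH+PTE 1 to 3, and the median was 0.65 without ICH+PTE 1 and 0.23 without ICH+PTE 2. Homeostatic microglia genes were lower in 4 of 13 and not called (median -0.21, adjusted p = 0.0993). They were called lower without ICH+PTE 2 (median -0.40, adjusted p = 0.00475). Some panel genes lost their call without single libraries. These were Il1b (1.0, adjusted p = 0.0203; 0.0592 without sham 1, 0.0552 without sham 2 and 0.0658 without ICH+PTE 2), Spp1 (1.78, 0.0327; 0.10 without sham 1, 0.107 without sham 3, 0.0992 without ICH+PTE 2 and 0.0870 without ICH+PTE 3), P2ry12 (-0.61, 0.0156; 0.0612 without sham 2) and Nlrp3 (0.58, 0.0334; 0.0582 without sham 1, 0.0515 without sham 2, 0.122 without sham 3, 0.0549 without ICH 2, 0.0523 without ICH 3, 0.0867 without ICH+PTE 2 and 0.0684 without ICH+PTE 3). The call of Il1b was also lost with all genes above 0 tested (0.0681), with quantile normalization (0.80, 0.0569) and with ICH+PTE 3 as the only treated library (0.228). That of Spp1 was also lost with all genes above 0 tested (0.117) and with only the 2 groups compared (0.0641). That of P2ry12 was also lost with ICH+PTE 3 as the only treated library (0.0824). That of Nlrp3 was also lost with all genes above 0 tested (0.0646), with quantile normalization (0.37, 0.125), with only the 2 groups compared (0.0745), with 2 libraries per group (0.0612) and with ICH+PTE 3 as the only treated library (0.141). Tmem119 was not called (-0.60, 0.115; 0.0475 without ICH+PTE 2 and 0.0325 with the replicate block).

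Matrix genes were higher in 12 of 17 (median log2 difference 1.43, camera adjusted p = 2.20e-09, adjusted p = 0.187 with an estimated correlation). Endothelial genes were higher in 7 of 14 (0.56, adjusted p = 6.05e-05, adjusted p = 0.235 with an estimated correlation), with the cadherin Cdh5 at 1.33. Mural and fibroblast genes were higher in 6 of 13 (0.52, adjusted p = 6.85e-05, adjusted p = 0.241 with an estimated correlation). NRF2 targets and antioxidant enzymes were higher in 10 and lower in 0 of 20 (0.45, adjusted p = 1.88e-05, adjusted p = 0.10 with an estimated correlation). In that list the glutathione transferase Gstm1 was at 0.78 and Nqo1 was not called (0.46, adjusted p = 0.0807; 0.0487 without ICH 3). Haem and iron genes were higher in 6 of 18 (0.26, adjusted p = 0.00245, adjusted p = 0.235 with an estimated correlation). Ferroptosis genes were higher in 4 of 12 (0.31, adjusted p = 6.17e-04, adjusted p = 0.140 with an estimated correlation). Apoptosis and p53 genes were higher in 7 of 13 (0.49, adjusted p = 0.00432, adjusted p = 0.187 with an estimated correlation), with the p53 target Cdkn1a at 2.08. Slc7a11 was called at 0.82 (adjusted p = 0.0114; 0.0872 with ICH+PTE 3 as the only treated library) and Gpx4 was not (-0.06, 0.788). Cell cycle genes were higher in 6 of 19 (0.61, adjusted p = 2.14e-04, adjusted p = 0.631 with an estimated correlation). The library means against sham were -0.05, 1.21 and 0.74 in ICH+PTE 1 to 3, and the median was 0.94 without ICH+PTE 1 and 0.32 without ICH+PTE 2. Ribosomal protein genes were higher in 7 of 27 (0.24, adjusted p = 1.78e-04, adjusted p = 0.638 with an estimated correlation), a call lost with ICH+PTE 3 as the only treated library (0.322). The library means against sham were 0.22, 0.57 and 0.10 in ICH+PTE 1 to 3, and the median was 0.10 without ICH+PTE 2 and 0.14 without sham 3. Mitochondrially encoded transcripts were higher in 4 of 13 (0.51, adjusted p = 1.78e-04, adjusted p = 0.463 with an estimated correlation). That call was lost with quantile normalization (median -0.01, 0.810) and with ICH+PTE 3 as the only treated library (0.0620). Nuclear-encoded oxidative phosphorylation genes were lower in 7 of 28 (-0.13, adjusted p = 0.0197, adjusted p = 0.691 with an estimated correlation). That call was lost with quantile normalization (0.294) and without sham 1 (0.272) or ICH+PTE 3 (0.203) and with 2 libraries per group (0.0927).

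All 16 striatal genes were lower than in sham (median log2 difference -1.48, camera adjusted p = 2.09e-11, adjusted p = 0.241 with an estimated correlation). Drd1 was at -1.47 (adjusted p = 0.00265; 0.0667 with ICH+PTE 3 as the only treated library) and Drd2 at -1.79. Pan-neuronal genes were lower in 5 of 22 (median -0.26) and the list lay just above the threshold (adjusted p = 0.0553). It was called lower without single libraries (adjusted p = 0.0319 without sham 1, 0.0280 without ICH 1, 0.0343 without ICH 2, 0.0132 without ICH+PTE 1 and 0.0372 without ICH+PTE 3). It was also called lower with the replicate block (0.0433) and with 2 libraries per group (0.00301). Slc32a1, the vesicular GABA transporter, was lower (-1.08). Cortical and hippocampal genes were higher in 2 of 12 and not called (adjusted p = 0.453). Thalamic and other subcortical genes rose in 6 of 12 (1.03, adjusted p = 0.00135, adjusted p = 0.293 with an estimated correlation), among them the kinase Prkcd (1.44) and the glutamate transporter Slc17a6 (1.26). Activity-regulated genes went both ways (2 higher and 5 lower of 11, not called), with Arc at -1.93. The lists of oligodendrocytes (1 higher and 4 lower), precursors (1 and 2), lysosome (4 and 0), glycolysis (1 and 4), homeostatic astrocytes (4 and 1), the unfolded protein response, heat shock, cholesterol, mitochondrial dynamics, ependyma, choroid plexus and erythroid cells were not called, and Mbp was not (-0.30, adjusted p = 0.412). Some of these lists were called without single libraries. Oligodendrocyte genes were called lower (adjusted p = 0.0497 without sham 2, 0.00958 without sham 3 and 0.0274 without ICH+PTE 2), as were choroid plexus genes (adjusted p = 0.0130 without sham 3, 0.0280 without ICH 1 and 0.0171 without ICH+PTE 1) and activity-regulated genes (adjusted p = 0.00398 without sham 3). Lysosome genes were called higher (adjusted p = 0.0306 without sham 1 and 0.0311 without ICH+PTE 1). Choroid plexus and lysosome genes were also called with the replicate block (0.00481 and 0.0444) and with 2 libraries per group (0.00397 and 0.0181). Lysosome genes were called with quantile normalization (0.0208) and rescaling by the median of ratios (0.0493). With ICH+PTE 3 as the only treated library, which holds more haemoglobin than the others (0.0920% of the summed FPKM against at most 0.0299%), erythroid genes were called higher (3.49e-04) and activity-regulated (0.0308) and choroid plexus genes (0.0345) lower.

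The comparison called 1736 genes higher and 1867 lower (23.4%), 493 and 298 of them by at least 2-fold, and the groups did not overlap for 38.6% of genes against 10% by chance. The count was 2258 without sham 2 and 2125 without sham 3. TPM moved the median of all genes by -0.12 and gave 1253 higher and 2972 lower. Camera called 22 lists higher and 2 lower of 41, fry called 20, and an estimated correlation left 0. Adjusted over the list alone, the counts were the same in 21 lists. In the other called lists the higher genes were 11 for monocytes, 11 for cytokines, 13 for NF-kappaB, 11 for complement, 9 for antigen presentation, 7 for thalamic neurons, 9 for endothelium, 8 for mural cells, 7 for haem, 12 for NRF2, 5 for ferroptosis, 7 for mitochondrially encoded transcripts, 14 for matrix and 8 for apoptosis, with 1 lower. In lists that were not called they were, higher and lower, 0 and 0 for cortical neurons, 2 and 6 for activity-regulated genes, 1 and 5 for precursors, 1 and 8 for glycolysis, 2 and 3 for heat shock and 3 and 3 for cholesterol.

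Genes changed by ICH mostly differed in the opposite direction between ICH+PTE and ICH. Of the genes that rose after ICH, 3772 (77.6%) were lower in ICH+PTE than in ICH, where independent lists would share 1480.8. Of those that fell 3319 (67.2%) were higher, against 1304.9. Together 7091 genes were called with opposite signs and 103 with the same sign. The 51 genes that rose in both steps and the 52 that fell in both lay, after PTE, further from sham than in ICH. Both comparisons hold the same 3 ICH libraries, which cannot be split into parts of at least 2, so part of the excess may come from them. Simulated groups without any effect gave a mean of 0.01 opposite calls and at most 1. With no ICH effect almost no gene is called in them. They therefore do not show how many opposite calls the shared libraries add when ICH differs from sham. The correlation across genes, which are not independent replicates, was -0.857 against -0.50 simulated, and the covariance -0.723 against -0.0177. ICH and ICH+PTE, each against sham, shared 1336 genes called higher and 1255 called lower, where independent lists would share 548.9 and 599.3. The correlation was 0.596 (0.50 simulated) and the covariance 0.323 (0.0177 simulated). Here too the 3 shared sham libraries may add to the excess.

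On the scale from sham (0) to ICH (1), built from a mean of 8804 genes chosen without the library placed, held-out sham libraries lay at 0.0222 ± 0.0825 and held-out ICH libraries at 0.985 ± 0.114 (mean ± SD, n = 3 each). The ICH+PTE libraries lay at 0.310 ± 0.109, with single values of 0.233, 0.435 and 0.263. An exact permutation test (two-sided, n = 3 against 3) gave p = 0.1 against ICH and p = 0.1 against sham, the smallest it can give, so this design cannot reach 0.05.

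Transcripts of some other organs differed between the ICH+PTE libraries and the others. Of the 24 small-intestine genes 14 were listed at 0 in all 6 sham and ICH libraries, and 18 separated all ICH+PTE libraries from the others. Chance would give 0.286 genes. That number is only a guide, since the test was chosen after the result was seen and the genes may not be independent. The sum of 15 liver transcripts such as albumin was 50.3 to 120 FPKM in ICH+PTE and 53.4 to 128 in the other libraries. The sum of Mup genes relative to it was 0.0251, 0.0512 and 0.121 in ICH+PTE 1 to 3 and 0.539 to 0.753 in the others. Airway transcripts summed to 25.5, 32.5 and 0.678 FPKM in ICH+PTE 1 to 3 against 0.632 to 4.77 elsewhere. Fat transcripts summed to 2.45 to 5.71 FPKM in ICH+PTE and 11.7 to 20.5 in the others. Kidney transcripts summed to 6.89, 8.64 and 0.650 FPKM in ICH+PTE 1 to 3 and 0.262 to 0.555 in the others. The sum of skeletal muscle transcripts, at 13 to 16.9 FPKM in ICH+PTE, lay within the range of the others (11.9 to 20.9). Pygm made up most of it in ICH+PTE, at 12.2, 14.6 and 11.3 FPKM against 4.31 to 7.82 in the others. Most of the other muscle genes were lower in each ICH+PTE library than in all the others. Examples are Acta1 (0.824 to 1.95 against 2.74 to 4.12 FPKM) and Ckm (0.0270 to 0.113 against 0.357 to 1.21). The sources used here name no separate library set. If the ICH+PTE libraries form such a set, it holds mice of 1 group only. The library set and the treatment then cannot be told apart, and no value within a set can be given.

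**Figure D3:**
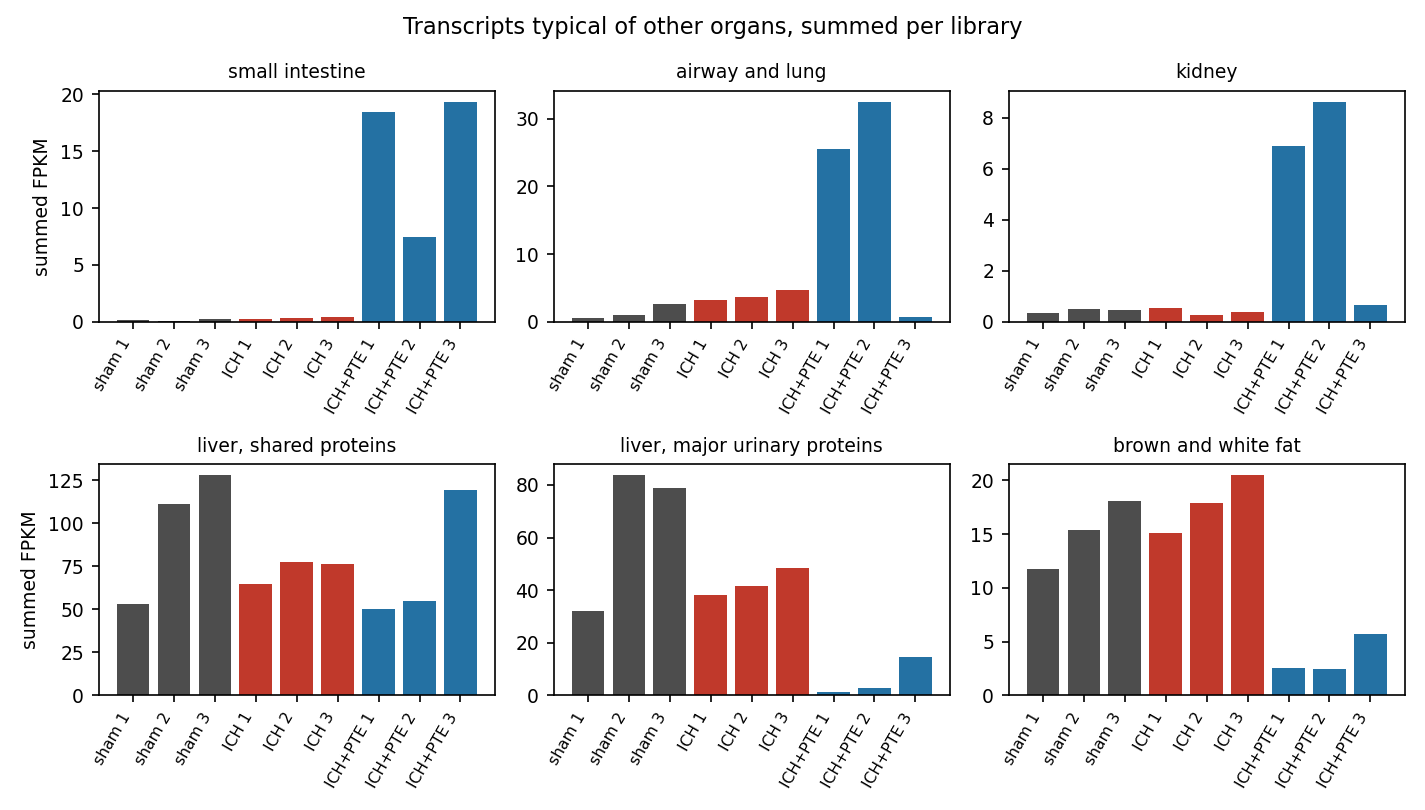
Summed FPKM of transcripts typical of 6 other organs or organ parts, with 1 bar per library coloured by group. The small-intestine bars of the ICH+PTE libraries reach 7.43 to 19.4 while all others stay at or below 0.443, and the bars of the major urinary proteins are lowest in ICH+PTE.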

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

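The fits with 2 libraries per group and with 1 treated library and some settings for terms, opposite calls and the position were chosen only after the result was seen. Of the counts of called genes, a minimum mean FPKM of 5, which left 8107 genes to test, gave 5684, 5247 and 2352 calls in ICH minus sham, ICH+PTE minus ICH and ICH+PTE minus sham, against 9798, 8748 and 3603, since fewer genes were tested. ICH+PTE 3 as the only treated library, assumed to vary like the other groups, gave 1322 in ICH+PTE minus sham, with fewer samples. The estimated correlation gave 0 called lists in all 3 comparisons and 0 called terms in both, for which the cause was not tested. A higher correlation is argued against for NRF2 targets and ferroptosis, whose estimates of -0.018 and -0.014 lie below the preset 0.01. In ICH+PTE minus sham their camera adjusted p still went from 1.88e-05 to 0.10 and from 6.17e-04 to 0.140. There fry gave adjusted p of 1.31e-04 for NRF2 targets and 2.54e-04 for ferroptosis. A call lost with the estimated correlation is therefore not in itself a sign that the genes of a list move together. Leaving out each library in turn gave 8511 to 10361, 7221 to 8765 and 2125 to 3712 called genes, 26 to 30, 23 to 25 and 24 to 27 called lists, 340 to 357 and 273 to 289 called terms, 5820 to 7158 opposite calls and positions between sham and ICH of 0.248 to 0.349. These fits kept 86.3% to 99.8%, 81.7% to 98.0% and 57.7% to 90.5% of the called genes, with 0 reversed. The replicate block gave 9925, 8945 and 3833 genes and 7267 opposite calls. Of the named genes, 15 of 172, 15 of 166 and 77 of 158 lost their call under at least 1 alternative, and 1 changed sign, Gfap in ICH+PTE minus ICH at 0.12 (adjusted p = 0.710) with quantile normalization, for which the cause was not tested. A count model on whole reads was not run, since whole read counts cannot be recovered from FPKM. Genes with an FPKM of at least 1 in fewer than 3 libraries were not tested.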

Other observations

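The tests of liver and intestine transcripts, of remaining shares, of subcortical genes and of the library set were chosen only after the result was seen, and the glucocorticoid pattern was noticed before its tests were set.

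ICH+PTE brains also held a group of genes above both other groups. In all 356 of the tested genes (2.32%) were called higher in ICH+PTE than in ICH and than in sham, 51 of them also higher in ICH than in sham and 227 not called between ICH and sham. Genes chosen after their values were seen include Plin4, a coat protein of lipid droplets, at 1.41 ± 0.893, 3.27 ± 3.03 and 15.4 ± 2.44 FPKM in sham, ICH and ICH+PTE (mean ± SD, n = 3 each), Pdk4, a brake on pyruvate oxidation, at 4.10 ± 0.0542, 5.98 ± 1.8 and 10.4 ± 1.89, and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 4.19 ± 0.837, 6.16 ± 1.67 and 11.3 ± 2.27. The metallothionein genes Mt1 and Mt2 rose in both steps, Mt2 from 101 ± 7.24 in sham to 490 ± 82.3 and 795 ± 224. Apod, a lipid-binding apolipoprotein, stood at 92.3 ± 11.8, 571 ± 254 and 852 ± 71.1, and Agt, the angiotensinogen made by astrocytes, at 13.9 ± 4.92, 21.2 ± 3.37 and 38.0 ± 2.73. In the opposite direction 543 genes were lower in ICH+PTE than in both other groups. Of these 377 were not called between ICH and sham, 114 were higher in ICH than in sham and 52 fell in both steps, among the last Hes5, a Notch target, at 5.70 ± 1.81, 1.48 ± 0.456 and 0.588 ± 0.0873.

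Genes of the circadian clock, listed later, were lower in ICH than in sham for 8 of 9 and higher in ICH+PTE than in ICH for 6 of 9. Nr1d1, a repressor of the clock, stood at 18.3 ± 2.61, 11.3 ± 2.24 and 24.5 ± 6.10 FPKM in sham, ICH and ICH+PTE, and Npas2, an activator, at 10.4 ± 1.45, 3.76 ± 1.11 and 6.63 ± 0.722.

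Small-intestine transcripts were higher and major urinary protein transcripts lower in the ICH+PTE libraries than in the other 6. Less liver RNA in the ICH+PTE libraries is argued against, since the median sum of shared liver proteins was 0.712 of that of the others and the ranges overlapped, while the Mup sum relative to it was at most 0.121 against at least 0.539. Of the 24 small-intestine genes 18 separated the groups, which may reflect traces of other tissues from another set of samples handled with the ICH+PTE libraries. Of these genes 1 was above 0 in all other libraries, Defa24 was at 2.92, 0.833 and 2.53 and Fabp6 at 2.39, 1.03 and 3.27 FPKM in ICH+PTE 1 to 3, and the sources used here give no date or lane. Whether such a set, which the sources used here do not name, also moved brain genes stays open, since it would coincide with the treatment.

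Phagocytic genes in ICH+PTE kept a median of 2.87% of the ICH minus sham FPKM difference (0.0776%, 6.43% and 2.97% in ICH+PTE 1 to 3) and reactive astrocyte genes 76.1% (67.8%, 83.4% and 79.5%), with wide and overlapping ranges of single genes, -4.51% (Apoe) to 38.1% (Csf1) and 23.4% (Vim) to 302% (Hspb1). Less of the injured tissue, diluted evenly with unaffected tissue, would leave the same share of both. The difference of the medians by 73.2 percentage points, with the medians apart in each library, argues against an even dilution as the whole cause. The lists were compared because they had been seen to differ. Whether some parts of the injured tissue were sampled less than others was not tested. Another part of the brain in the ICH+PTE samples may add to the pattern, since 6 of 12 thalamic and other subcortical genes were called higher than in sham. A smaller phagocyte response in treated mice, the 2.87% left, cannot be told apart from a different library set, which would coincide with the treatment. A different region, which the sources used here do not give, stays open.

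Genes known to be induced by glucocorticoids were higher in ICH+PTE than in both other groups for 10 of 11 that had been seen before. Their values were known when they were listed, so this count is no test. Of 11 others 3, Tsc22d3, Errfi1 and Ddit4, were called higher than in both, where chance gives 0.255 (Fisher's exact test, p = 0.00177, which takes genes as independent and so overstates the evidence). In all 5 of these 11 were called higher than in ICH, Klf9 and Per1 among them, and 8 higher than in sham, but Xdh and Cebpd were lower than in ICH and Sgk1, Bcl6, Gpd1 and Fam107a not called against it, so a wider response stays open. A different time of day of collection may play a part and cannot be told apart, as 4 of 9 clock genes were called against sham. Arntl, Npas2 and Per2 were lower and Ciart was higher. Arntl, Npas2 and Per2 were also lower in ICH than in sham (-0.98, -1.39 and -0.98, against -0.73, -0.61 and -0.78 in ICH+PTE). Their fall against sham is therefore not particular to ICH+PTE. The median log2 difference of the 11 others was 0.51 in ICH+PTE minus ICH, and a different set of libraries or handling cannot be told apart from the treatment.

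For the counts of called genes the 10 splits of the 6 libraries are too few for a share under 0.05. The real counts were 9798, 8748 and 3603 in ICH minus sham, ICH+PTE minus ICH and ICH+PTE minus sham, and the highest of the other splits gave 0, 1 and 0, so 1, 1 and 1 splits reached the real count. For gene lists other splits called more lists than the real one, 32, 27 and 27 at most against 29, 25 and 24, and 3, 2 and 4 of the 10 splits, too few for a share under 0.05, gave as many or more. For annotation terms, again with too few splits, the real counts were 351 and 279 and the highest others 291 and 258, with 1 and 1 as large. Each of the other splits mixes mice of both groups and so keeps part of the real group difference. Camera compares the genes of a list or term with the other genes, so calls can persist in such splits. They therefore do not show how many lists or terms would be called with no group difference. Of 100 splits of the 9 libraries drawn from 840, 1 gave as many opposite calls, the real one with 7091. The highest other gave 1. That share is under 0.05, but the other splits mix ICH mice with the rest, which widens the spread within groups. Few genes of any kind are then called. The splits therefore do not show how much the shared ICH libraries add to the count.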
